A study of Mus musculus with 60 samples.

How the data were processed

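The series holds 60 RNA-seq libraries of mouse hippocampus, the cortical fold that serves memory and stress control. Per the labels, female mice of 2 months were injected with melanoma cells that cause cachexia (the CAC group), with melanoma cells that do not (NCAC), or with no tumour cells (mock injection, Con). Cachexia is a wasting syndrome of cancer with loss of muscle and fat, of which no measure was used here. Tissue was taken 2, 4, 6 and 8 wk after injection. At these times there were 4, 5, 5 and 7 CAC libraries, 5, 5, 4 and 5 NCAC libraries, and 5 Con libraries each. The labels call them biological replicates, and replicate numbers are those of the labels, so that CAC at 2 wk holds replicates 1, 2, 4 and 5. The labels disagree on the strain: the sample labels name C57BL6/J, and the series' design text names NCI Ath/nude. The extract protocol also names another tumour line, which matches no group.

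Per the labels' protocols, RNA was taken with Trizol, libraries were made with the TruSeq stranded mRNA kit, which selects polyadenylated RNA and keeps the strand, and sequencing was on a NovaSeq 6000. The authors deposited a single table of TPM, a transcript abundance scaled by gene length and library total, with 1 value per gene symbol and library for 47643 symbols, and the values of every library have the same sum. Per the submitters' processing notes, the genome build was mm10. The aligner, the counting tool, the annotation release and the use of strand in counting are not given in the sources used here. TPM divides reads by gene length and by each library's own total, so a change in a few very abundant genes shifts all others the opposite way. It also keeps any difference between libraries in the recovery of short or GC-rich transcripts. Genes that share sequence with near-identical copies, such as histone genes, ribosomal protein pseudogenes and Cwc22 with its predicted copies, can exchange reads, and their values are uncertain.

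TPM keeps no depth of its own, but in this table the values of each gene were whole multiples of a step set by gene and library. Within a tolerance of 0.02 of a read, whole reads were recovered for all 24227 genes above 0 in at least 1 library (100.00%), with gene lengths of which 61.6% equalled the exon union of GENCODE mouse release M21 and 71.7% lay within 5% of it, among the 15037 tested genes with a single annotated gene of that symbol. The recovered depth was 32388193 to 42046784 reads per library. The spread between libraries sets the errors given.

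The main test was limma 3.58.1 in R 4.3.3 on log2(TPM + 0.5), with an intensity trend in the variance. Group means for the 12 groups were fitted over all 60 libraries, so that every comparison shared an estimate of the spread, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Genes with a TPM of at least 1 in at least 4 libraries were tested, 15608 in all. Differences are on the log2(TPM + 0.5) scale, which understates the change of low genes, and are given with their standard error (SE) from limma. Adjusted p-values of single genes are limma's. Comparisons were CAC with Con, CAC with NCAC and NCAC with Con at each time, the same pairs over the mean of the 4 times, the change of the tumour differences from 2 wk to 8 wk, and Con at 8 wk against Con at 2 wk.

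Before the data were examined, 46 gene lists for hippocampal cell types, neighbouring brain regions, blood, and stress, immune and metabolic responses were fixed from textbook knowledge. So were the rule for named genes, the comparisons, and all alternatives not said to be added later. For CAC against Con at each time, the named genes were the 10 with the largest positive and the 10 with the largest negative difference among those past the threshold, and 5 and 5 in the other comparisons. Predicted or clone-named genes and genes under a mean of 1 TPM in the higher group were left out of that ranking. Where no gene passed, the 3 genes with the smallest p were named as values. From each list described, 2 to 4 members with the smallest p were named. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 46 lists. Camera was run again with the correlation estimated from the data: of the 220 list calls over the 18 comparisons, 0 held. Members of a list were also adjusted over the list alone. Under median-of-ratios scaling, 35 list calls were lost and 0 changed direction.

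After the data were seen, these were added: removal of the trend on GC content and gene length from each library with natural splines of 5 degrees of freedom each, for the 15062 tested genes with a known GC content (96.5%); fits without libraries rich in striatum or blood genes; limma's voom on the recovered reads with median-of-ratios scaling; thalamus and striatum covariates; and two-sided exact permutation tests on the mean log2 of a list per library. A library was set aside in the second of these when its mean of the striatum list lay over 1 log2, or its mean of the erythrocyte list over 1.5 log2, above the median of all libraries. That named replicate 1 of CAC at 2 wk, replicates 1 and 4 of CAC at 4 wk, replicate 3 of CAC at 8 wk, replicate 2 of Con at 4 wk and replicate 5 of NCAC at 4 wk. Such permutation tests cannot go below p = 0.00794 with 5 against 5 or 4 against 5 libraries, or 0.00126 with 7 against 5.

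Within groups no library was a copy of another: the closest pair differed by 9.2 times or more what sampling alone gives. Data were simulated for 6 comparisons, with 50 of 15608 genes changed per fold size. The fit found 62% to 80% of genes changed 1.5-fold and 84% to 94% changed 2-fold. Error rates in real libraries were not tested. False calls were 1.7% to 3.7%, but 8.6% for CAC against Con at 6 wk and 6.6% for NCAC against Con at 8 wk. Gene positions are those of GENCODE M21 on GRCm38 (mm10).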

Results

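RNA was measured in the hippocampus of mice injected with melanoma cells labelled as causing cachexia (CAC), with melanoma cells labelled as not (NCAC), or with a mock injection (Con), at 2, 4, 6 and 8 wk. Each of the 12 groups held 4 to 7 libraries, 60 in all, at 32388193 to 42046784 recovered reads per library. No label says that each library is a different mouse, so p-values measure the spread between these samples. Values are TPM with the SD over a group's libraries, and differences are log2 with their SE. Every call of a gene list rests on camera's preset correlation, and none held with an estimated correlation.

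CAC mice differed from mock-injected mice in more genes at 8 wk than at any other time. Etnppl, an astrocyte enzyme that breaks down phosphoethanolamine, was 12.7 ± 6.29 TPM in CAC (SD, n = 7) and 0.693 ± 0.361 in Con (n = 5), a 9.23-fold rise on the tested scale (log2 difference 3.21 ± 0.49 SE, adjusted p = 0.000239). Scgb3a1, a secreted secretoglobin, rose by 3.11 ± 0.49, and Plin4, a coat protein of lipid droplets, by 2.99 ± 0.65. Gkn3, a marker of arterial endothelium in the brain, averaged 0.856 TPM in CAC and 5.66 in Con and fell by 2.29 ± 0.36 (adjusted p = 0.000239). Fabp7, the fatty acid-binding protein of radial glia and astrocytes, averaged 27.9 TPM in CAC and 71.2 in Con and fell by 1.44 ± 0.27. On GRCm38, Etnppl lies on chromosome 3 at 130617448 to 130637521 on the plus strand, and Gkn3 on chromosome 6 at 87383256 to 87388935 on the minus strand.

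In all, 2256 of 15608 genes passed at 8 wk, 1757 higher and 499 lower in CAC, of which 99 differed over 2-fold. With median-of-ratios scaling there were 1409 calls, 679 higher and 730 lower. Other genes with the largest rises were Rtp1, a chaperone of odorant receptors (2.51 ± 0.45), Hif3a, a hypoxia-pathway factor (2.00 ± 0.44), the stress kinase Map3k6 (1.90 ± 0.38), Tmem252 (1.85 ± 0.33), the sulfotransferase Sult1a1 (1.78 ± 0.34) and Lcn2, an iron-binding protein of inflammation (1.83 ± 0.32). The pseudogene Apoo-ps rose by 2.55 ± 0.76 but did not pass with voom or with only the compared groups. Among the falls were Myoc, a secreted glycoprotein (−1.92 ± 0.39), Scand1 (−1.74 ± 0.53), the interferon-induced GTPase Tgtp2 (−1.50 ± 0.39) and the leukocyte gene Lst1 (−1.44 ± 0.41). Igkc, an immunoglobulin light chain, fell by 3.09 ± 0.70, with 30.8 ± 58.6 TPM in Con (SD, n = 5) and 135 in its replicate 5. Hist1h2al, Hist2h2aa2 and Hist1h2bk, replication-dependent histone sequences poorly captured by poly(A) selection, differed by −1.86 ± 0.60, −1.67 ± 0.52 and −1.57 ± 0.55, and none passed after GC and length correction. Replicate 3 of CAC had 0.995 TPM of Etnppl where the other 6 libraries held 10.1 to 20.1, and its erythrocyte list lay 3.12 log2 above the median library.

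**Figure D1:**
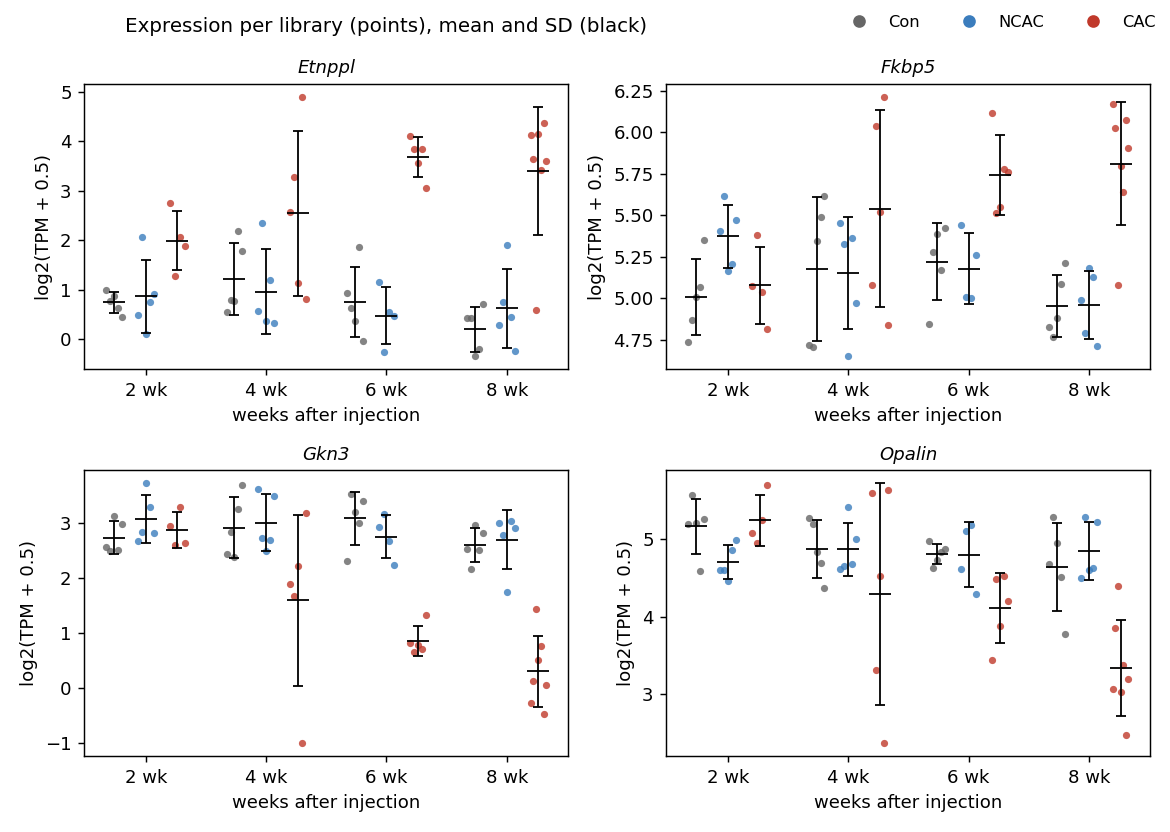
Levels of Etnppl, Fkbp5, Gkn3 and Opalin as log2(TPM + 0.5) against weeks after injection, with a point per library and the mean ± SD per group.

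Targets of glucocorticoids, the adrenal stress hormones, were higher in CAC at 8 wk. Of 23 measured members 13 rose, or 17 adjusted over the list alone (camera, adjusted p = 9.9e-08, and adjusted p = 0.54 with an estimated correlation). Examples were the kinase Sgk1, at 94.7 ± 14.9 TPM in CAC (SD, n = 7) and 41.7 ± 3.95 in Con (n = 5, log2 difference 1.16 ± 0.21), the cell-cycle inhibitor Cdkn1a (1.65) and Pdk4, which limits glucose oxidation (1.00 ± 0.19). The mean of the list was higher in 6 of 7 CAC libraries than in every Con library (5.19 ± 0.41 against 4.35 ± 0.17 log2, exact permutation p = 0.00758, adjusted 0.0436). The list of IL6 (a cytokine), STAT3 (its transcription factor) and acute inflammation was also higher. Of 18 members 7 rose, 7 adjusted over the list alone (adjusted p = 0.044, and adjusted p = 0.607 with an estimated correlation). They included Ch25h, which makes an oxysterol in inflammation (1.74 ± 0.30), the acute-phase gene Lrg1 (1.63) and the oncostatin receptor Osmr (0.88). All 7 CAC library means of this list lay above the Con range (2.52 ± 0.15 against 2.17 ± 0.13, exact permutation p = 0.00505, adjusted 0.0332). The camera call for it was lost in 5 of the 12 fits that left out a library, with adjusted p up to 0.129, and was 0.0601 without the striatum-rich and blood-rich libraries (the rich libraries). In the circadian clock list, 5 of 17 members rose, among them Cry1 (0.53) and Cry2 (0.23), and adjusted over the list alone 8 rose and 1 fell (0.025, and adjusted p = 0.607 with an estimated correlation).

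Several lists were lower in CAC at 8 wk. The interferon response and antigen presentation genes fell in 4 of 23, 5 adjusted over the list alone (adjusted p = 5.41e-06, and adjusted p = 0.54 with an estimated correlation). They were led by B2m, the light chain of MHC class I (−0.71), and the proteasome subunits Psmb8 and Psmb9 (both −0.65). Meningeal fibroblast markers fell in 2 of 11, 5 adjusted over the list alone, with the collagen Col3a1 and the retinoic acid enzyme Aldh1a2 both at −0.96 (7.1e-05, and adjusted p = 0.54 with an estimated correlation). Myelinating oligodendrocyte genes fell in 3 of 14, 4 adjusted over the list alone, with the myelin protein Opalin at −1.30 ± 0.32 (0.000797, and adjusted p = 0.616 with an estimated correlation). Of 18 neuropeptide and neurotrophin genes, Npy (−0.58 ± 0.13) and Cck (−1.10 ± 0.29) fell, 2 adjusted over the list alone. That list had an adjusted p of 0.000797, adjusted p = 0.326 with an estimated correlation, and all 7 CAC library means lay below Con (4.31 ± 0.07 against 4.6 ± 0.04, exact permutation p = 0.00126, adjusted 0.0332). Neurogenesis genes fell in 3 of 15, 3 adjusted over the list alone, with the progenitor filament Nes at −0.84 ± 0.15 and the proliferation marker Mki67 at −0.46 (0.00204, and adjusted p = 0.54 with an estimated correlation).

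Markers of resting microglia, the brain's immune cells, fell in 2 of 12, 2 adjusted over the list alone, namely Olfml3 (−1.08) and the purine receptor P2ry13 (−0.60). The list's adjusted p was 0.000848, and adjusted p = 0.54 with an estimated correlation. Activated microglia markers fell in 2 of 18, 3 adjusted over the list alone, with lysozyme (Lyz2, −1.06) and the MHC class II gene H2-Aa (−1.39), and perivascular macrophage markers in 1 of 7, 1 adjusted over the list alone. Camera gave 0.000972 and 0.044, and with an estimated correlation adjusted p = 0.54 and adjusted p = 0.616. Cholesterol synthesis genes were called lower with Dhcr7 (−0.26) and Hmgcs1 (−0.28) falling and Lss (0.20) rising, of 21, the same counts adjusted over the list alone (adjusted p = 0.000797, and adjusted p = 0.616 with an estimated correlation). Pericyte and smooth muscle genes (0.00382, and adjusted p = 0.54 with an estimated correlation) and immediate early genes (0.0112, and adjusted p = 0.672 with an estimated correlation) were called lower with 0 members past the threshold, 0 adjusted over the list alone.

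Nuclear oxidative phosphorylation (OXPHOS) genes were called lower although 5 of 36 rose and 4 fell, 6 and 6 adjusted over the list alone. Mitochondrially encoded (mt-encoded) genes fell in 2 of 13, 3 adjusted over the list alone, and cytosolic ribosomal protein genes were called lower with 4 of 37 rising and 1 falling, 4 and 1 adjusted over the list alone. Adjusted p were 0.00204, 0.00204 and 0.00623, and with an estimated correlation adjusted p = 0.711, adjusted p = 0.586 and adjusted p = 0.835. These lists moved with a technical trait of the libraries. The slope of a library's deviation on gene length, in log2 per doubling, was −0.1037 to −0.0898 in the 5 Con libraries of 8 wk. After removal of the GC and length trend, all were over the threshold (0.587, 0.646 and 0.989), as were the clock, immediate early (both 0.0547) and perivascular macrophage lists (0.115), the last 2 also with median-of-ratios scaling. For the comparison at 8 wk, the gene count ranged from 1034 to 3070 when single libraries were left out, with the lowest without replicate 2 of CAC. It was 3527 without the rich libraries, and single libraries decided the calls of the ribosomal protein (up to 0.0552 without one), immediate early (0.0729), clock (0.0765) and perivascular macrophage lists (0.192).

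**Figure D2:**
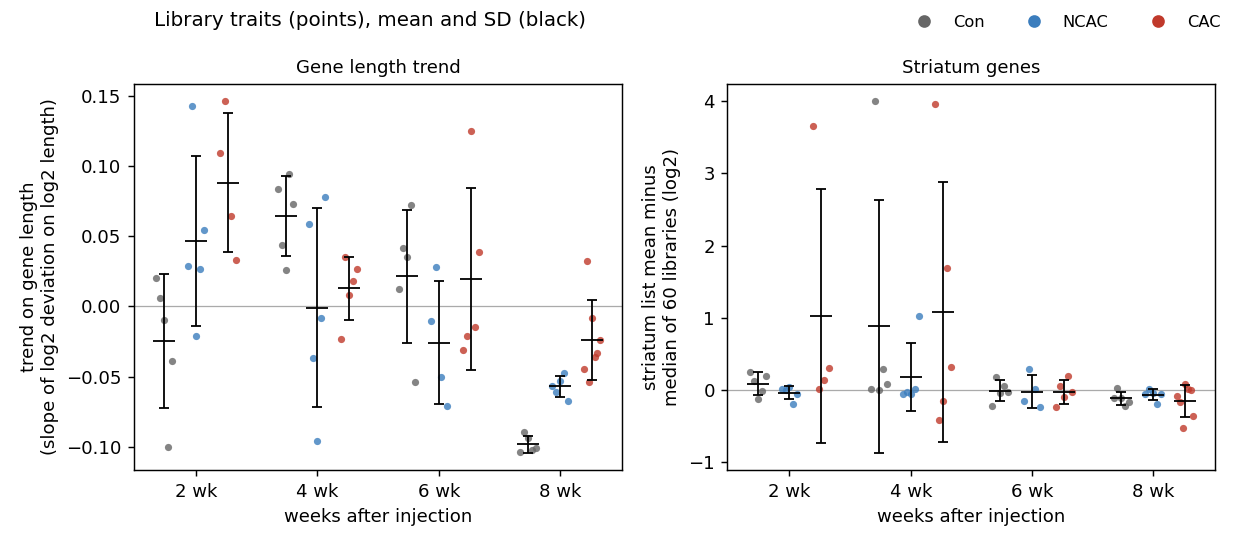
Slope of each library's log2 deviation on log2 gene length, and its mean of the striatum list minus the median of all libraries (log2), for all 60 libraries by group and week. Replicate 2 of Con at 4 wk lies at 4.00 in the striatum list.

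At 6 wk, 39 of 15608 genes differed between CAC and Con, 28 higher and 11 lower. Etnppl was 12.7 ± 3.39 TPM in CAC (SD, n = 5) against 1.37 ± 1.04 in Con (n = 5), a rise of 2.93 ± 0.53 log2 (SE, adjusted p = 0.00975). Gkn3 was 1.34 ± 0.384 TPM against 8.36 ± 2.58 and fell by 2.23 ± 0.39 (adjusted p = 0.00721). Among the other rises were Rtp1 (2.28 ± 0.49), the Wnt ligand Wnt10b (1.80 ± 0.43), Lrg1 (1.76 ± 0.35), Ch25h (1.38 ± 0.32), the dioxygenase-like Phyhd1 (1.38 ± 0.28) and the endothelial surface gene Ly6a (1.20 ± 0.29). Scgb3a1 rose by 2.67 ± 0.53 and Cdkn1a by 1.41 ± 0.33. Nes (−0.77 ± 0.17), the vascular peptide Apln (−0.71 ± 0.16), the axon guidance receptor Dcc (−0.60 ± 0.12), Vegfa, the main growth factor of blood vessels (−0.59 ± 0.13), and the heparin-binding growth factor Ptn (−0.53 ± 0.10) fell. Of the genes named here only Etnppl and Gkn3 passed in every alternative and in every fit without a library; Cdkn1a lost the call in 9 of 10 fits without a library, Wnt10b, Ly6a and Apln in 8, Ch25h in 7, Vegfa in 6 and Nes in 5, and Scgb3a1, Rtp1, Lrg1, Cdkn1a and Ch25h with voom. Without single libraries 9 to 85 passed, lowest without replicate 1 of CAC. Without the rich libraries, none of 6 wk, 145 did, as only the shared spread changed.

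The glucocorticoid response list was called higher at 6 wk, with 4 of 23 members rising and 10 adjusted over the list alone (adjusted p = 1.87e-09, and adjusted p = 0.452 with an estimated correlation), among them Sgk1 (0.96) and Pdk4 (0.95). All 5 CAC libraries lay above Con in the list mean (5.16 ± 0.25 against 4.51 ± 0.12, exact permutation p = 0.00794, adjusted 0.183). The IL6 and STAT3 list rose in 5 of 18, 7 adjusted over the list alone, including Osmr (0.86), Socs3, the feedback inhibitor of STAT3 (0.97), and Bcl3 (1.05). Its adjusted p was 5.38e-06, and adjusted p = 0.219 with an estimated correlation. The reactive astrocyte list (1 of 15 rising, and adjusted over the list alone 4 rising and 1 falling) and the complement list (1 of 11, 1 adjusted over the list alone, C4b at 0.97) were called higher as well. Their adjusted p were 0.00727 and 0.00958, adjusted p = 0.602 with an estimated correlation for both, and both calls were lost without replicate 2 of CAC (0.138 for the first, and up to 0.542 for the second). The cold-inducible RNA-binding genes Rbm3 and Cirbp were called higher with 0 of 2 past the threshold, 2 adjusted over the list alone (adjusted p = 0.0294, adjusted p = 0.452 with an estimated correlation, and up to 0.119 without a library). The choroid plexus list, from tissue that makes cerebrospinal fluid and lies against the hippocampus, was higher by a median of 1.31 with 0 of 12 passing, 0 adjusted over the list alone (0.00538, adjusted p = 0.731 with an estimated correlation, and 0.0509 without replicate 4 of Con).

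Neurogenesis genes were called lower at 6 wk, with Nes falling among 15 and 3 adjusted over the list alone (adjusted p = 0.0128, and adjusted p = 0.452 with an estimated correlation). Pericyte and smooth muscle genes were called lower with 0 of 10 past the threshold, 2 adjusted over the list alone (3.01e-05, and adjusted p = 0.452 with an estimated correlation). Cholesterol synthesis (0 of 21), presynaptic (0 of 18) and heat shock genes (0 of 13) were called lower with 0 adjusted over the list alone. The adjusted p were 0.000134, 0.0064 and 0.0202, and with an estimated correlation adjusted p = 0.648, adjusted p = 0.66 and adjusted p = 0.648; the heat shock call was lost in 2 of 10 fits without a library (up to 0.17).

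**Figure D3:**
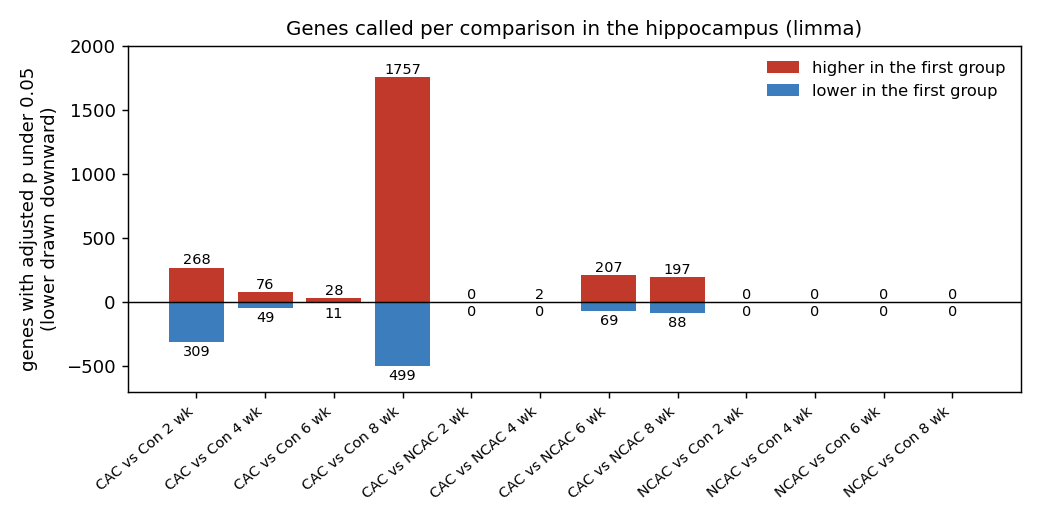
Number of genes at adjusted p under 0.05, higher and lower, in each of the 12 pairwise comparisons of groups within a week. CAC against Con at 8 wk has 1757 higher and 499 lower.

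Against NCAC, 285 genes differed in CAC at 8 wk, 197 higher and 88 lower. Scgb3a1 rose by 3.13 ± 0.49 (adjusted p = 0.000236) and Etnppl by 2.78 ± 0.49, with 12.7 TPM in CAC (n = 7) and 1.27 in NCAC (n = 5). Rtp1 rose by 2.41 ± 0.45 and Tmem252 by 2.02 ± 0.33. Gkn3 fell by 2.40 ± 0.36 (adjusted p = 0.000105), Serpinb1a, an inhibitor of neutrophil proteases, by 1.42 ± 0.23, Fabp7 by 1.24 ± 0.27 and Serpind1, a thrombin inhibitor, by 1.13 ± 0.28. Opalin was 10.5 ± 5.17 TPM in CAC and 29.1 ± 7.89 in NCAC (SD) and fell by 1.51 ± 0.32 (adjusted p = 0.0077). Plin4 rose by 2.56 ± 0.65 (adjusted p = 0.0261); it lost the call in 7 of 12 fits without a library, Serpind1 in 4, and Fabp7 with only the compared groups. The count ranged from 72 (without replicate 5 of NCAC) to 714 (without replicate 3 of CAC), and was 83 with only the compared groups and 1086 without the rich libraries.

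Glucocorticoid response genes rose in 8 of 23, 15 adjusted over the list alone, in CAC against NCAC at 8 wk (adjusted p = 1.75e-13, and adjusted p = 0.245 with an estimated correlation). Fkbp5, which dampens the glucocorticoid receptor, was 57.1 ± 12.9 TPM in CAC (SD, n = 7) and 30.8 ± 4.39 in NCAC (n = 5, log2 difference 0.85 ± 0.18), and Cdkn1a (1.53) and Map3k6 (1.89) rose as well. The list mean of 6 of 7 CAC libraries lay above the NCAC range (5.19 ± 0.41 against 4.42 ± 0.18, exact permutation p = 0.0114, adjusted 0.0747). The IL6 and STAT3 list rose in 6 of 18, 8 adjusted over the list alone, with Lrg1 (1.79) and Ch25h (1.57), at adjusted p = 1.72e-06, and adjusted p = 0.0885 with an estimated correlation. Its library means were 2.52 ± 0.15 against 2.05 ± 0.11, with all 7 CAC libraries above NCAC (exact permutation p = 0.00126, adjusted 0.029). Complement genes rose in 2 of 11, 4 adjusted over the list alone, namely C4b (1.01) and C4a (0.60), with adjusted p = 0.00424, and adjusted p = 0.459 with an estimated correlation. Reactive astrocyte genes rose in 3 of 15, with 5 rising and 1 falling adjusted over the list alone, including Lcn2 (1.94) and Serpina3n (0.38). That list had an adjusted p of 0.0106, and adjusted p = 0.55 with an estimated correlation.

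Myelinating oligodendrocyte genes fell in 4 of 14, 9 adjusted over the list alone, in CAC against NCAC at 8 wk. They were Opalin, the aspartoacylase Aspa (−0.65), the galactolipid enzyme Ugt8a (−0.95) and the connexin Gjb1 (−0.82), at adjusted p = 1.15e-09, and adjusted p = 0.379 with an estimated correlation. Neuropeptide and neurotrophin genes fell in 2 of 18, 3 adjusted over the list alone, namely Npy (−0.63) and Bdnf (−0.48). Their adjusted p was 3.84e-05, adjusted p = 0.0799 with an estimated correlation, and library means were 4.31 ± 0.07 against 4.6 ± 0.07 (exact permutation, adjusted 0.029). Of 21 cholesterol synthesis genes Hmgcs1 fell (−0.35), 2 adjusted over the list alone (adjusted p = 1.86e-06, and adjusted p = 0.459 with an estimated correlation). Of 15 neurogenesis genes Nes fell (−0.90), 3 adjusted over the list alone (0.00968, adjusted p = 0.379 with an estimated correlation, and 0.0997 without replicate 5 of NCAC). Of 12 resting microglia genes P2ry13 fell (−0.74), 2 adjusted over the list alone (0.0147, and adjusted p = 0.593 with an estimated correlation). Oligodendrocyte precursor (OPC) genes were called lower with 0 of 11 passing, 4 adjusted over the list alone (0.0106, adjusted p = 0.459 with an estimated correlation, and 0.0898 without replicate 5 of NCAC). Meningeal fibroblast (0.000588), pericyte (0.0106), mt-encoded (0.0147), OXPHOS (0.0314) and GABAergic neuron lists (0.0495) were called lower too, with adjusted p = 0.55 to adjusted p = 0.884 with an estimated correlation. Of these, 1 GABAergic gene fell, 1 adjusted over the list alone, and the others had 0 by both counts. The mitochondrial lists were at 0.827 and 0.25 after GC and length correction. The pericyte (up to 0.0618), resting microglia (0.0798) and GABAergic calls (0.215) were lost without single libraries.

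**Figure D4:**
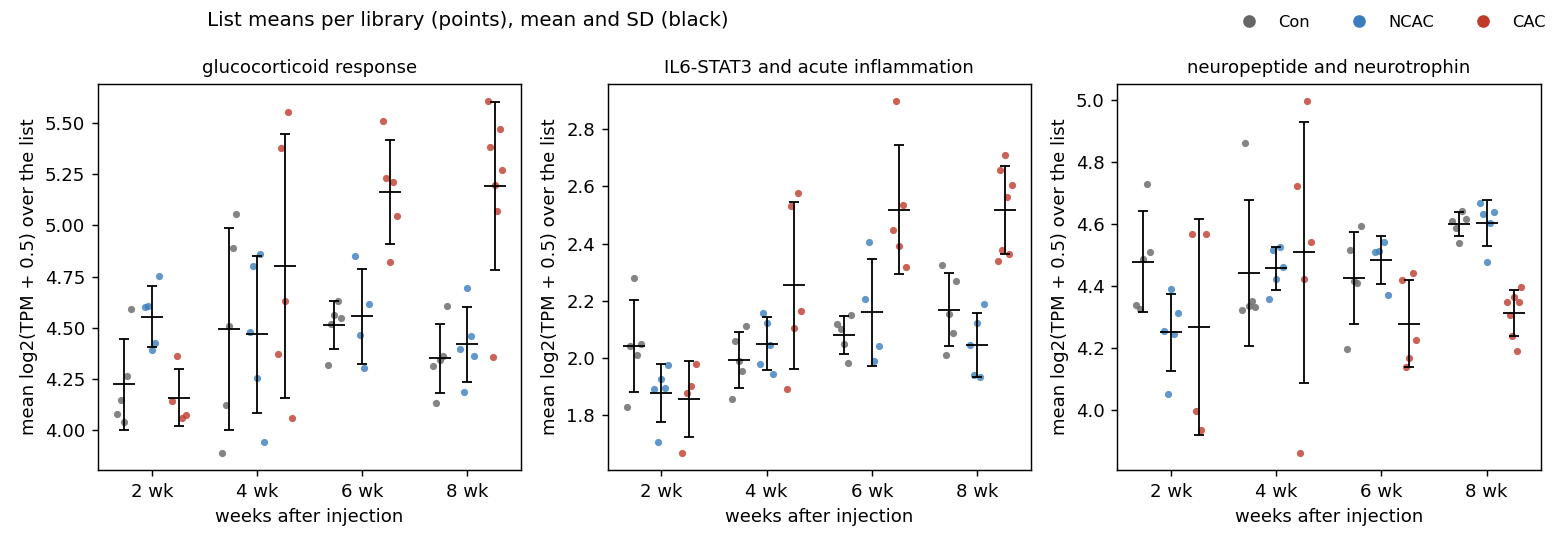
Mean log2(TPM + 0.5) of the glucocorticoid response, IL6 and STAT3, and neuropeptide and neurotrophin lists in each library against weeks after injection, by group with mean ± SD.

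At 6 wk, 276 genes differed between CAC and NCAC, 207 higher and 69 lower (265 with median-of-ratios scaling, 158 and 107). Etnppl averaged 12.7 TPM in CAC (n = 5) and 0.972 in NCAC (n = 4) and rose by 3.21 ± 0.57 (SE, adjusted p = 0.00261). Rtp1 (2.63 ± 0.52), Wnt10b (2.20 ± 0.46) and Tmem252 (1.54 ± 0.38) rose, and Scgb3a1 rose by 2.47 ± 0.57. Gkn3 (−1.90 ± 0.41), the microglial receptor Fcrls (−1.39 ± 0.34), the signalling adaptor Dok6 (−1.28 ± 0.36), the peptidase Lnpep (−1.24 ± 0.35) and the mitotic kinase Pbk (−1.06 ± 0.20) fell. Scgb3a1, Dok6 and Lnpep lost the call with voom, and in 2, 7 and 7 of 9 fits without a library, Tmem252 in 6 and Fcrls in 5. Without single libraries 43 to 367 passed, lowest without replicate 3 of NCAC. Only the compared groups gave 96, and 605 passed without the rich libraries (none of 6 wk).

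In that comparison at 6 wk, glucocorticoid response genes rose in 4 of 23, 10 adjusted over the list alone, among them Sgk1 (0.97) and Pdk4 (1.00). The list was at adjusted p = 0.000151, and adjusted p = 0.69 with an estimated correlation. The list mean lay above the NCAC range in 4 of 5 CAC libraries (5.16 ± 0.25 against 4.56 ± 0.23, exact permutation p = 0.0238, adjusted 0.274). IL6 and STAT3 genes rose in 4 of 18, 5 adjusted over the list alone, with Socs3 (1.13) and Osmr (0.93). The list was at adjusted p = 0.00341, adjusted p = 0.549 with an estimated correlation, and 0.0644 without replicate 2 of CAC. Of 17 clock genes 2 rose, among them Cry1 (0.51), 5 adjusted over the list alone, and Rbm3 (0.70) was 1 of 2 cold-inducible genes, 2 adjusted over the list alone. Their adjusted p were 0.012 and 0.0128, and with an estimated correlation adjusted p = 0.69 and adjusted p = 0.549. Of 15 neurogenesis genes Top2a (−0.71) fell, 2 adjusted over the list alone (0.012, and adjusted p = 0.549 with an estimated correlation). Cholesterol synthesis (0.000151), meningeal fibroblast (0.000393), OXPHOS (0.00101), erythrocyte (0.012), mt-encoded (0.012), neuropeptide (0.0168) and pericyte lists (0.0168) were called lower with no member falling. With an estimated correlation these ran from adjusted p = 0.549 to adjusted p = 0.795. Adjusted over the list alone, cholesterol synthesis and OXPHOS each had 1 rising and 1 falling and the rest 0; over all genes, 1 of 36 OXPHOS genes rose. Calls lost without single libraries were those of the OXPHOS (up to 0.292), pericyte (0.282), mt-encoded (0.112), clock (0.0729) and neuropeptide lists (0.0689). Lost after GC and length correction were mt-encoded (0.916) and neuropeptide (0.148).

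At 2 wk, 577 of 15608 genes differed between CAC and Con, 268 higher and 309 lower (503 with median-of-ratios scaling, 76 and 427). Prkcd, a kinase abundant in thalamic neurons, averaged 63.6 TPM in CAC (n = 4) and 23.0 in Con (n = 5) and rose by 1.13 ± 0.27 (SE, adjusted p = 0.0248). Zic1, a transcription factor of the developing brain, rose (1.21 ± 0.37). Rab37 (1.09 ± 0.31), the actin-binding Synpo2 (0.85 ± 0.24) and Plekhg1 (0.71 ± 0.21) rose mainly in CAC replicate 1. Romo1, a small mitochondrial membrane protein (−1.76 ± 0.46), the complex III subunit Uqcrq (−1.47 ± 0.35), the mitochondrial ribosomal protein Mrpl52 (−1.65 ± 0.40) and the ribosomal protein Rpl36 (−1.42 ± 0.32) fell. Hist1h2al, a pseudogene, was the largest fall (−2.59 ± 0.69). Calls were 178 after GC and length correction, 9 without the rich libraries and 2 to 1279 without single libraries. They were 0 with thalamus and striatum covariates or only the compared groups.

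Of 37 ribosomal protein genes 11 fell, 24 adjusted over the list alone, and of 36 nuclear OXPHOS genes 15 fell, with 25 falling and 3 rising adjusted over the list alone, in CAC against Con at 2 wk. Camera gave 1.34e-16 and 2.3e-16, and adjusted p = 0.383 with an estimated correlation for both. The length slopes of the 4 CAC libraries of 2 wk were 0.0331 to 0.1463, but both lists held after GC and length correction (4.41e-07 and 6.42e-12). Thalamus markers rose in 4 of 11, 9 adjusted over the list alone, with Rora at 0.65, at adjusted p = 3.16e-06, adjusted p = 0.383 with an estimated correlation, and 0.103 without the rich libraries. Replicate 1 of CAC held 51.9 TPM of Plekhg1 where the others held 11 to 13.8, and its striatum list lay 3.65 log2 above the median. Npy (−0.62) and Sst (−0.90) fell among 18 neuropeptide genes, 4 adjusted over the list alone (0.00413, adjusted p = 0.383 with an estimated correlation, and 0.309 after GC and length correction). Of 13 mt-encoded genes 1 fell, 2 adjusted over the list alone, and of 23 interferon response genes 0 passed, 0 adjusted over the list alone. They were called lower at 0.00727 and 0.00246, adjusted p = 0.847 with an estimated correlation for both, and both calls were lost without replicate 5 of CAC (0.12 and up to 0.148).

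At 4 wk, 125 genes differed between CAC and Con, 76 higher and 49 lower. The nuclear noncoding RNA Malat1 averaged 483 TPM in CAC and 307 in Con and rose by 0.63 ± 0.15 (SE, n = 5 and 5, adjusted p = 0.0419). Spaca6 (0.90 ± 0.22), the small isomerase Pin4 (0.77 ± 0.19), Sap30l (0.71 ± 0.15) and the complex I subunit Ndufb4 (0.65 ± 0.16) rose. Kdr, the main VEGF receptor, was 5.68 ± 2.22 TPM against 9.32 ± 1.65 (SD) and fell by 0.72 ± 0.18, as did Apln (−0.75 ± 0.16), the endothelin Edn3 (−0.81 ± 0.20), the phosphatase Alpl (−0.97 ± 0.23) and the Wnt exporter Wls (−0.60 ± 0.13). None passed without the rich libraries (0), without replicate 4 of CAC or without replicate 4 of Con, while 590 passed without replicate 5 of CAC, 42 with a choroid plexus covariate and 31 with thalamus and striatum covariates.

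Ribosomal protein genes rose in 4 of 37, 28 adjusted over the list alone, in CAC against Con at 4 wk, among them Rps24 (0.57 ± 0.13) and Rps14 (0.43 ± 0.09), and OXPHOS genes in 3 of 36, with 15 rising and 1 falling adjusted over the list alone. Camera gave 8.33e-20 and 7.07e-10, and with an estimated correlation adjusted p = 0.373 and adjusted p = 0.609. Choroid plexus genes were lower by a median of −2.39 log2, with 0 of 12 passing and 12 adjusted over the list alone (4.54e-08, and adjusted p = 0.609 with an estimated correlation). Ependymal genes were called lower with 0 of 9, 3 adjusted over the list alone (0.00113, adjusted p = 0.643 with an estimated correlation, and 0.896 with a choroid plexus covariate). Of 21 cholesterol synthesis genes Idi1 (−0.49 ± 0.12) and Nsdhl (−0.39 ± 0.09) fell, 9 adjusted over the list alone, and of 13 heat shock genes Hsph1 (−0.40 ± 0.10) and Hsp90aa1 (−0.24 ± 0.06) fell, with 6 falling and 1 rising adjusted over the list alone. Their adjusted p were 1.91e-08 and 0.0092, and with an estimated correlation adjusted p = 0.609 and adjusted p = 0.643. Resting microglia (0.000181, 4 adjusted over the list alone), oligodendrocyte (0.00653, 0 adjusted over the list alone) and stress response lists of unfolded proteins (0.0092, 0 adjusted over the list alone) were called lower with 0 members passing. Glucocorticoid response (0.00653) and cold-inducible genes (0.00653) were called higher with 0 members passing, each with 2 adjusted over the list alone. Without the rich libraries these were at 0.0818, 0.142, 0.055, 0.291 and 0.0591, and with an estimated correlation they ran from adjusted p = 0.373 to adjusted p = 0.709.

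Between CAC and NCAC, 2 genes passed at 4 wk and 0 at 2 wk. Otof, a calcium sensor of vesicle release, averaged 8.99 TPM in CAC and 4.38 in NCAC at 4 wk and rose by 0.94 ± 0.18, and Bzrap1, a presynaptic scaffold, rose by 0.37 ± 0.07 (SE, n = 5 and 5, adjusted p = 0.0442 for both). Neither passed without the rich libraries or with only the compared groups, and the count ran from 0 to 180 without single libraries. With limma on log2(TPM + 0.5), 0 genes passed at 2 wk, where 1083 had an unadjusted p under 0.05, and voom called 0. The smallest p at 2 wk were those of Tcf7l2, a transcription factor of thalamic neurons (1.11 ± 0.25), Spink8 (−0.74 ± 0.17) and Fam134b (0.26 ± 0.06), all at adjusted p = 0.437.

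Of the lists, 12 were called for CAC against NCAC at 2 wk and 20 at 4 wk, with 0 members past the threshold over all genes. With an estimated correlation they ran from adjusted p = 0.0914 to adjusted p = 0.896 at 2 wk and from adjusted p = 0.384 to adjusted p = 0.59 at 4 wk. Thalamus (4.34e-13, 10 of 11 adjusted over the list alone), striatum (7.6e-05), oligodendrocyte (7.6e-05) and fasting genes (0.0446, 2 of 16 adjusted over the list alone) were called higher at 2 wk. Called lower at 2 wk were the glucocorticoid response (5.23e-09, median −0.32), OXPHOS (2.56e-06), ribosomal protein (4.57e-05), immediate early (0.00336), interferon response (0.0138), heat shock (0.0394), unfolded protein response (0.0446) and excitatory neuron lists (0.0468), with 0 members adjusted over the list alone. The striatum call was at 0.89 without replicate 1 of CAC. Of 9 fits without a library, 6 lost the excitatory neuron and fasting calls, 5 heat shock and unfolded protein, 3 interferon, and 2 ribosomal protein and immediate early. All but heat shock were also lost after GC and length correction.

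At 4 wk, cholesterol synthesis (1.28e-08, 7 of 21 adjusted over the list alone), ependymal (1.67e-05, 2 of 9), heat shock (0.0013, 1 of 13) and hypoxia genes (0.0218, 2 of 15) were called lower in CAC than in NCAC. Lower with 0 members adjusted over the list alone were interferon response and oligodendrocyte (both 5.29e-06), choroid plexus (2.05e-05, median −1.44), resting microglia (2.93e-05), meningeal fibroblast (0.00298), unfolded protein response (0.00321), activated microglia (0.00392), pericyte (0.0092), and OPC, excitatory neuron and immediate early genes (each 0.0218). Higher were the clock (0.00145, 2 of 17 adjusted over the list alone) and cold-inducible genes (0.00392, 2 of 2), striatum (0.00281), glucocorticoid response (0.00493) and GABAergic genes (0.0478). Without the rich libraries 9 calls were lost: striatum (0.953), glucocorticoid, GABAergic, clock, pericyte, meningeal, OPC, excitatory neuron and immediate early. Of 10 fits without a library, 7 lost the GABAergic call, 4 immediate early, and 3 glucocorticoid, pericyte, OPC and excitatory neuron.

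With limma, 0 genes passed for NCAC against Con at 2, 4, 6 and 8 wk and for the mean of the 4 times, where 1517, 1538, 587, 1226 and 379 genes had an unadjusted p under 0.05, and voom called 0 in each. With sample quality weights, 154 passed at 4 wk, 792 at 8 wk and 1 for the mean. The smallest p were those of Pxylp1 (0.30 ± 0.06, adjusted p = 0.161), Vstm2b (−0.47 ± 0.11) and Slc25a44 (0.19 ± 0.05) at 2 wk, and of the protease Klk8 (0.55 ± 0.11, adjusted p = 0.227), Tube1 (−0.44 ± 0.10) and the kinase subunit Prkacb (−0.29 ± 0.07) at 4 wk. At 6 wk they were those of Gtse1 (0.61 ± 0.15), Lars2 (0.46 ± 0.12) and Gm4491 (−0.80 ± 0.22, adjusted p = 0.973), and at 8 wk of Ccdc36 (−1.16 ± 0.29), Rpl10 (0.38 ± 0.10) and Btbd10 (0.20 ± 0.05, adjusted p = 0.634). For the mean they were Mknk1 (0.10 ± 0.03), RP23-74K24.2 (0.49 ± 0.14) and Gm9774 (0.59 ± 0.17).

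Lists called for NCAC against Con had 0 members past the threshold over all genes. At 8 wk, interferon response (9.82e-08), complement (2.78e-06), activated microglia (8.83e-05), immediate early (0.00785), choroid plexus (0.0184) and IL6 and STAT3 genes (0.0347) were called lower with 0 adjusted over the list alone, and lymphocyte and neutrophil genes (0.00668) with 1 of 4 adjusted over the list alone, S100a8 at −1.23 ± 0.39. These ran from adjusted p = 0.176 to adjusted p = 0.902 with an estimated correlation. Of 10 fits without a library, 5 lost the IL6 and STAT3 call and 4 immediate early and choroid plexus. At 2 wk, ribosomal protein (5.31e-13), OXPHOS (7.04e-11), neuropeptide and complement (both 0.00788), oligodendrocyte (0.0186), ependymal (0.0278), mt-encoded (0.0298) and choroid plexus genes (0.0438) were called lower, with 0 adjusted over the list alone. The clock list was called higher (0.000615), with 6 of 17 rising and 1 falling adjusted over the list alone, Cry1 at 0.50 ± 0.13, as were glucocorticoid response (0.0012, 0 adjusted over the list alone) and presynaptic genes (0.00912, 1 adjusted over the list alone). These ran from adjusted p = 0.644 to adjusted p = 0.896 with an estimated correlation. Of 10 fits without a library, 6 lost the choroid plexus call, 5 mt-encoded, 4 oligodendrocyte and 3 ependymal. Choroid plexus, ependymal, neuropeptide, presynaptic and mt-encoded calls were lost after GC and length correction.

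At 4 wk, ribosomal protein genes were called higher in NCAC than in Con (3.86e-22, 14 of 37 adjusted over the list alone, Rps24 at 0.50 ± 0.13), as were OXPHOS (3.3e-15, 5 of 36), interferon response (0.00125) and excitatory neuron genes (0.0487), and striatum genes lower (0.0487), with adjusted p = 0.52 to adjusted p = 0.983 with an estimated correlation. At 6 wk, choroid plexus (2.09e-06, median 1.33), ependymal (0.00283), meningeal fibroblast (0.0073), OXPHOS (0.00879), mt-encoded (0.0222) and dentate granule cell genes (0.0266) were called higher and clock genes lower (0.00879). All were at 0 adjusted over the list alone, with adjusted p = 0.879 to adjusted p = 0.905 with an estimated correlation. Of 9 fits without a library, 4 lost the meningeal, OXPHOS (0.755 after GC and length correction) and dentate calls, and at 4 wk 5 of 10 lost excitatory neuron and 4 striatum. For the mean of the times, complement (3.1e-05), resting microglia (0.00614), activated microglia (0.017), interferon response (0.0193), lymphocyte and cortex (both 0.0317), CA1 (0.0298), striatum (0.0317) and GABAergic genes (0.0493) were called lower and glucocorticoid response (0.00579), CA2 and CA3 (0.00614), dentate (0.0317) and meningeal genes (0.0493) higher. All were at 0 adjusted over the list alone, with adjusted p = 0.295 to adjusted p = 0.927 with an estimated correlation. Of 39 fits without a library, 25 lost the GABAergic call, 20 meningeal, 12 dentate, 10 CA1 and striatum, 6 interferon and cortex, 5 lymphocyte, 2 activated microglia and 1 glucocorticoid.

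Over the 4 times, Etnppl averaged 9.62 TPM in CAC (n = 21) and 1.33 in Con (n = 20) and rose by 2.18 ± 0.27 (SE, adjusted p = 1.11e-06), and Scgb3a1 (1.72 ± 0.27), Plin4 (1.51 ± 0.35), Rtp1 (1.43 ± 0.24) and Tmem252 (1.08 ± 0.18) rose. Gkn3 fell by 1.43 ± 0.19 (adjusted p = 6.16e-06), Igkc by 1.45 ± 0.38 and Myoc by 1.05 ± 0.21. In all, 3095 genes passed, 2323 higher and 772 lower (2580 with median-of-ratios scaling, 1328 and 1252). Against NCAC, 2446 passed, 1804 higher and 642 lower (2250 with that scaling, 1195 and 1055). There Etnppl rose by 2.17 ± 0.27 and Gkn3 fell by 1.48 ± 0.20.

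For CAC against Con over the 4 times, glucocorticoid response genes rose in 11 of 23 (15 adjusted over the list alone), with Sgk1 at 0.60 ± 0.11. Clock genes rose in 7 of 17 (8 rising and 1 falling adjusted over the list alone), with Cry2 at 0.20 ± 0.03. IL6 and STAT3 genes rose in 7 of 18 (7 rising and 1 falling adjusted over the list alone), with Osmr at 0.60 ± 0.08 and Lrg1 at 1.03 ± 0.17. Rbm3 (0.48 ± 0.07) and Cirbp (0.35 ± 0.08) both rose, 2 adjusted over the list alone, and 5 of 11 markers of CA2 and CA3 pyramidal cells rose (5 adjusted over the list alone), with Cacng5 at 0.55 ± 0.17. The adjusted p of these lists were 4.78e-06, 0.0113, 0.0173, 0.00938 and 0.0329, and with an estimated correlation adjusted p = 0.49, for the cold-inducible genes adjusted p = 0.465. The IL6 and STAT3 call was at 0.0528 without replicate 2 of CAC at 6 wk.

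Lower over the 4 times against Con were cholesterol synthesis (8 of 21 falling and Lss rising, 12 and 1 adjusted over the list alone, Msmo1 at −0.27 ± 0.06), neuropeptide (5 of 18, 5 adjusted over the list alone, Npy at −0.31 ± 0.07), neurogenesis (4 of 15, 4 adjusted over the list alone, Nes at −0.50 ± 0.08) and resting microglia genes (3 of 12, 4 adjusted over the list alone, Olfml3 at −0.70 ± 0.14). Their adjusted p were 1.06e-06, 0.00149, 0.0232 and 0.000506, and with an estimated correlation adjusted p = 0.49, for the neuropeptides adjusted p = 0.418. Interferon response (2.41e-05, 3 of 23), mt-encoded (0.00196, 3 of 13), heat shock (0.00283, 2 of 13), pericyte (0.00445, 1 of 10), activated microglia (0.0104, 2 of 18), meningeal fibroblast (0.0113, 1 of 11), oligodendrocyte (0.0282, 3 of 14) and ependymal genes (0.0441, 1 of 9) were lower too, with 3, 3, 3, 1, 0, 1, 3 and 1 adjusted over the list alone. OXPHOS (0.00445, 5 of 36 falling and 4 rising, 7 and 4 adjusted over the list alone), immediate early (0.0113) and choroid plexus genes (0.0282), both with 0 by either count, were also called lower. With an estimated correlation these ran from adjusted p = 0.49 to adjusted p = 0.709. Median-of-ratios scaling and GC and length correction each ended 7 calls: activated microglia, oligodendrocyte, choroid plexus, ependymal and immediate early in both, meningeal and neurogenesis in the first, and OXPHOS and mt-encoded in the second. Of 41 fits without a library, 14 lost the ependymal call and 7 oligodendrocyte and choroid plexus.

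Against NCAC over the 4 times, 21 lists were called, with adjusted p = 0.398 to adjusted p = 0.632 with an estimated correlation. Higher were glucocorticoid response (0.0016, 9 of 23, 9 adjusted over the list alone, Fkbp5 at 0.38 ± 0.10), IL6 and STAT3 (0.0025, 7 of 18, 8 adjusted over the list alone, Socs3 at 0.63 ± 0.11), complement (0.0285, 3 of 11, 3 adjusted over the list alone, C4b at 0.82 ± 0.11), clock (0.0215, 6 rising and 1 falling of 17, the same adjusted over the list alone) and cold-inducible genes (0.0079, 2 of 2, 2 adjusted over the list alone). Lower were cholesterol synthesis (6.97e-07, 7 of 21 falling and 1 rising, 9 and 1 adjusted over the list alone), neuropeptide (0.0025, 5 of 18, 7 adjusted over the list alone, Bdnf at −0.26) and meningeal fibroblast genes (0.000601, 3 of 11, 4 adjusted over the list alone, Dcn at −0.34). Of 15 hypoxia and vascular growth genes Apln (−0.48 ± 0.08), Vegfa (−0.33 ± 0.07) and Ldha (−0.18 ± 0.03) fell and Hif3a (0.71 ± 0.24) rose, the same adjusted over the list alone (0.0471, lost in 19 of 40 fits without a library, up to 0.0958). The other lists called lower were OXPHOS (0.000608), interferon response (0.0025), heat shock (0.00377), mt-encoded (0.00864), oligodendrocyte (0.0114), neurogenesis and pericyte (both 0.0244), resting microglia and immediate early (both 0.0285), unfolded protein response (0.033), OPC (0.0341) and ependymal genes (0.0452). Of 40 fits without a library, 17 lost the ependymal call, 6 immediate early and OPC, 4 unfolded protein, 3 resting microglia and pericyte, and 2 complement. Ependymal, immediate early, OPC, resting microglia and hypoxia calls were lost with median-of-ratios scaling and after GC and length correction, pericyte with the first, and clock, unfolded protein and mt-encoded after the second.

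From 2 to 8 wk, the difference between CAC and Con changed for 1 gene. Spink8, a protease inhibitor of hippocampal neurons, went from 38.4 ± 8.54 to 104 ± 11.6 TPM in CAC (SD, n = 4 and 7) and from 82.8 ± 5.30 to 77.2 ± 10.1 in Con (n = 5 and 5), a change of the difference of 1.56 ± 0.23 (SE, adjusted p = 0.000217). The change against NCAC passed for 37 genes, 20 higher and 17 lower, among them Scgb3a1 (3.29 ± 0.75), the death receptor Fas (1.37 ± 0.29), Serpinb1a (−1.80 ± 0.35) and Enpp6, an enzyme of newly forming oligodendrocytes (−1.42 ± 0.30). Named genes of the change against NCAC lost the call in 4 to 16 of 21 fits without a library, Scgb3a1 and Atp2c2 most often. The count against Con was 18 without replicate 3 of CAC at 8 wk, and that against NCAC ran from 1 to 138 without single libraries, was 171 without the rich libraries and 110 after GC and length correction.

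The glucocorticoid response had the smallest p of all lists for the change from 2 to 8 wk against NCAC, with Fkbp5 rising (1.15 ± 0.27), 1 of 23, and 20 adjusted over the list alone (adjusted p = 1.11e-21, and adjusted p = 0.124 with an estimated correlation). Against Con 0 of 23 passed, 13 adjusted over the list alone (1.25e-12, and adjusted p = 0.315 with an estimated correlation). Oligodendrocyte genes moved down against NCAC with 0 of 14, 11 adjusted over the list alone (3.23e-13, and adjusted p = 0.184 with an estimated correlation). IL6 and STAT3 genes moved up with 4 of 18 adjusted over the list alone against NCAC (7.95e-05, and adjusted p = 0.184 with an estimated correlation) and 5 rising and 1 falling adjusted over the list alone against Con (0.000187, and adjusted p = 0.315 with an estimated correlation). Thalamus genes moved down with 8 and 7 of 11 adjusted over the list alone (1.32e-08 and 1.64e-08, adjusted p = 0.184 and adjusted p = 0.315 with an estimated correlation).

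Other lists were called for that change without a member passing, save Nes (−1.14 ± 0.24) in neurogenesis against NCAC (0.0484, lost in 8 of 21 fits without a library). Against Con these were oligodendrocyte down (1.29e-05), ribosomal protein (3.64e-07) and OXPHOS (2.67e-06) up and reactive astrocyte up (0.0289, lost in 7 of 21), and down meningeal fibroblast (7.6e-07, 6 of 11 adjusted over the list alone), pericyte (0.000293), neurogenesis and cholesterol synthesis (both 0.00535), striatum (0.00542, but 0.91 without replicate 1 of CAC at 2 wk), extracellular matrix (0.00826) and resting microglia (0.0103), with adjusted p = 0.381 to adjusted p = 0.723 with an estimated correlation. Against NCAC they were cholesterol synthesis (0.0002), pericyte (0.00287), striatum (0.00287, but 0.54 without that library) and meningeal fibroblast (0.0124, lost in 2 of 21) down, and clock and reactive astrocyte (both 0.0163, lost in 3 and 2) and CA1 genes (0.0484, 3 of 7 adjusted over the list alone, lost in 9) up, with adjusted p = 0.597 to adjusted p = 0.677 with an estimated correlation.

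In mock-injected mice, 1509 genes differed between 8 and 2 wk, 261 higher and 1248 lower (984 with median-of-ratios scaling, 501 and 483). The haemoglobin gene Hba-a2 rose by 3.37 ± 1.07 (SE, n = 5 and 5, adjusted p = 0.0373), Scand1 by 2.62 ± 0.57, Erdr1 by 2.36 ± 0.61, Ccdc85b by 2.27 ± 0.58 and the prohormone inhibitor Pcsk1n by 1.96 ± 0.56. Apoo-ps (−3.82 ± 0.82), the plasma protein genes Alb (−2.47 ± 0.81), Apoa2 (−1.63 ± 0.51) and Ahsg (−1.36 ± 0.43), and the urinary protein gene Mup2 (−1.41 ± 0.37) fell. After GC and length correction 35 passed, Scand1 and Apoo-ps alone of those named, and Hba-a2, Alb and Apoa2 lost the call in 7 of 10 fits without a library and Ahsg in 6. The count ran from 173 to 2546 without single libraries, the lowest without replicate 1 of Con at 2 wk.

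In the same comparison of Con, of 36 OXPHOS genes 6 rose and 2 fell, 8 and 2 adjusted over the list alone (2.56e-07). Of 20 immediate early genes Egr4 (1.38 ± 0.36) and Junb (1.29 ± 0.36) rose, 2 adjusted over the list alone (5.91e-05). Of 14 oligodendrocyte genes Mal (−0.70 ± 0.18) and Mobp (−0.61 ± 0.18) fell, 7 adjusted over the list alone (0.00596, and up to 0.168 without a library). The ribosomal protein (0.00233, 1 of 37 rising and 2 falling, 3 and 2 adjusted over the list alone), glucocorticoid response and interferon response lists (both 0.0413, 1 of 23 rising, 0 adjusted over the list alone) were called higher. The glucocorticoid list had a median of 0.0 and a mean of 0.13, and its call was lost in 5 of 10 fits without a library, interferon in 6 (up to 0.461), and both with median-of-ratios scaling (0.278). After GC and length correction both and ribosomal protein (0.886) were lost. All 6 were at adjusted p = 0.955 with an estimated correlation.

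The comparisons with Con and NCAC share the CAC libraries, which by itself makes the differences alike. At 8 wk, 172 genes were higher and 70 lower in both, and 0 opposite, where independent calls would give 22.2 and 2.8. Simulations without any effect gave 0, also where no library is shared, so this tests nothing. With CAC libraries split to share none, 16.1 were called in both on average. Across genes, which are not independent replicates, r was 0.71 against 0.40 in simulations, and the covariance 0.0413 against 0.00911, a difference of 0.0322, with 0.0315 in the split. The comparisons of CAC with Con at 6 and 8 wk share no library: 26 genes were higher and 7 lower in both, where independent calls would give 3.2 and 0.4.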

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

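The tests of the GC and length trend on gene counts, of the scaling, of the time of day and of Cwc22 were chosen only after the results they measure were seen; outcomes of the others were written down before they were run. For the glucocorticoid list, the outcome written beforehand was an adjusted exact p under 0.05. It was over that value with and without most settings, so the share of the difference that was left and the unadjusted exact p were used, a choice made after the result was seen.

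Many genes differed between CAC and Con at 8 wk, where the 5 Con libraries lie apart from the other libraries of 8 wk in length slope. Against a GC and length trend as the main cause, 1587 genes passed once it was removed, 1230 of them among the 2256, whereas for Con at 8 wk against 2 wk 35 passed, 24 of them among the 1509. Of the 242 genes also called in the same direction against NCAC, 83.1% passed against Con of 2, 4 and 6 wk. Selection and shared CAC libraries favour this, so it decides nothing. Of the other 2014 genes 17.9% passed, 12.8% of the 1585 higher and 36.6% of the 429 lower. Of uncalled genes 18.3% passed in either direction, so the 1585 could belong to the Con libraries of 8 wk and the 429 stay open. The surplus of higher genes is tied to the scaling, since 48.2% were higher with median-of-ratios scaling.

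Thalamus or striatum tissue in the dissection could account for calls of CAC against Con at 2 and 4 wk. With both list means as covariates 0 passed at 2 wk and 31 at 4 wk (30 among the 125), while all 2256 of 8 wk held, among 2556. Calls did not track rich libraries alone: without replicate 4 of Con, not rich, 2 passed at 2 wk and 0 at 4 wk. Without rich replicate 1 of CAC, 4 and 216 did. The GC and length trend fits at 2 wk (178 against 577, 124 in both), not 4 wk (218 against 125). The covariates also carry some group difference, so an early tumour effect in these genes cannot be told apart from dissection.

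The glucocorticoid response list was higher in CAC than in NCAC at 6 and 8 wk, which would fit a rise of stress hormones in cachexia, not measured in these files. Without the GC and length trend, the difference of the list mean was 0.61 at 6 wk (exact permutation p = 0.0159, adjusted 0.219) and 0.77 at 8 wk (p = 0.00758, adjusted 0.0436). After regression on the choroid plexus list it was 0.61 (exact permutation p = 0.0159, adjusted 0.292) and 0.78 (p = 0.00884, adjusted 0.0581), so neither accounts for it. Corticosteroids also follow the time of day, which the labels do not give: the median difference of Dbp, Nr1d1, Per2 and Ciart was −0.1 at 6 wk and −0.01 at 8 wk. At 6 wk Dbp (−0.45 ± 0.19) and Ciart (0.36 ± 0.21) lay opposite ways, neither past the threshold, and the clock list was called higher, so a difference in time of day stays open.

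Relabelled splits of the compared libraries tested whether chance alone can give as many genes. For CAC against Con it is excluded at 2 wk (2 of 100 splits reached the real 577, the real one included, and the highest other split gave 925), at 6 wk (3, 39, 243) and at 8 wk (1, 2256, 1236), but not at 4 wk (10, 125, 464). Against NCAC it held at 6 wk (1, 276, 250) and 8 wk (2, 285, 312), but not at 4 wk (20, 2, 599). A real count of 0, as against NCAC at 2 wk (highest other 873) and for NCAC against Con (0, 8, 12 and 2 at the 4 times, 26 for the mean), is reached by all 100 splits by construction and tests nothing. Only the real split reached the means of CAC against Con (1, 3095, 21) and NCAC (1, 2446, 226). So it was for Con at 8 wk against 2 wk (1, 1509, 922). For the changes from 2 to 8 wk against Con (3, 1, 2) and NCAC (4, 37, 1239), splits decide nothing. They also remove a constant group difference. Where other splits called several times the real number, a structure of the samples besides the groups is a possible reason, not tested.

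Single libraries far from the rest of their group were searched for among the named genes, and 19 of 238 tested groups held one, where chance gives about 1 in 20. In CAC at 8 wk, replicate 3 had 0.995 TPM of Etnppl (others 10.1 to 20.1), 2.53 of Plin4 (28.5 to 60.4), 0.74 of Rtp1 (4.38 to 9.79) and 12.6 of Sult1a1 (38.0 to 71.8). In CAC at 2 wk, replicate 1 had 51.9 of Plekhg1 and 3.44 of Fign (0.855 to 1.09), and replicate 5 had 4.15 of Hist1h2al where the others had 0. Snrpe was 22.8 in replicate 5 of CAC at 4 wk, Apln 13.8 in replicate 3 of Con at 4 wk and Gkn3 2.02 in replicate 5 of CAC at 6 wk. In NCAC at 8 wk, replicate 3 had 1.54 of Rtp1 and 2.87 of Gkn3. In Con at 8 wk, replicate 2 had 2.53 of Alb, 1.73 of Apoa2 and 0.692 of Ahsg, replicate 4 had 1.83 of Apoo-ps, and replicate 5 had 45.9 of Fabp7. In Con at 2 wk, replicate 4 had 5.55 of Scand1 and 0 of Apoo-ps.

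Tumour differences changed from 2 to 8 wk (limma). Against Con 1 gene passed, Spink8 (1.56). Against NCAC 37 passed, among them Scgb3a1 (3.29), Rtp1 (3.02), Tmem252 (2.27), Atp2c2 (1.64), Fas (1.37), Serpinb1a (−1.80), Enpp6 (−1.42), Lpar1 (−1.27), Mcam (−1.25) and Bche (−1.15).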

How the results depend on the processing

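The GC and length correction, the fits without libraries rich in striatum or blood genes, voom, the thalamus and striatum covariates and the exact permutation of list means were chosen after seeing the data. Where a count below moved by over 1.5 times or past 0, the cause was not tested. Fits of fewer libraries have fewer values to test with, yet some called more genes. Without the rich libraries CAC vs Con 8 wk gave 3527 against 2256. With a pseudocount of 0.1 or 1, all 18 gene counts stayed within 1.5 times the reported ones. With genes at a mean TPM of 5 or more, 16 of 18 did, and CAC vs Con 6 wk gave 22 and the CAC vs NCAC change from 2 to 8 wk 16. Without a filter, CAC vs Con 2 wk gave 298 and 4 wk 40, CAC vs NCAC 4 wk 0, 6 wk 174 and the change 16, and NCAC vs Con 8 wk 1. With median-of-ratios scaling, CAC vs Con 4 wk gave 213 and 8 wk 1409, CAC vs NCAC 4 wk 6 and the change 93, and Con 8 wk vs 2 wk 984. With voom 16 of 18 stayed, CAC vs Con 2 wk gave 294 and the CAC vs NCAC change 77. The choroid plexus covariate gave 42 for CAC vs Con 4 wk, and thalamus and striatum covariates 0 at 2 wk and 31 at 4 wk.

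Sample quality weights moved most counts upward. CAC vs Con gave 1042, 793, 228 and 5277 at 2, 4, 6 and 8 wk and 51 for the change, CAC vs NCAC 0 at 4 wk, 516 at 6 wk, 1485 at 8 wk and 207 for the change, NCAC vs Con 154 at 4 wk, 792 at 8 wk and 1 for the mean, and Con 8 wk vs 2 wk 4870. With only the compared groups, CAC vs Con gave 0 at 2 wk and 37 at 4 wk, CAC vs NCAC 0, 96 and 83 at 4, 6 and 8 wk, NCAC vs Con 5 at 8 wk, and Con 8 wk vs 2 wk 3166. After GC and length correction, CAC vs Con gave 178, 218 and 114 at 2, 4 and 6 wk and 5 for the change, CAC vs NCAC 22, 444 and 455 at 4, 6 and 8 wk and 110 for the change, and Con 8 wk vs 2 wk 35. Without the rich libraries (none of 6 wk), CAC vs Con gave 9, 0, 145 and 3527 at the 4 times and 14 for the change. CAC vs NCAC gave 0, 605 and 1086 at 4, 6 and 8 wk and 171 for the change. Libraries with the same replicate number were not alike (of 56 pairs 11 had a residual r over 0.1, from −0.28 to 0.35, with mean 0), so the number marks no pairs. With it as a block, CAC vs Con gave 280 at 2 wk and 988 at 8 wk, CAC vs NCAC 10 at 4 wk, 51 at 8 wk (without Opalin, at 0.0721, Plin4 and Serpind1) and 0 for the change, and 3 lists for NCAC vs Con 4 wk.

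Leaving out a library at a time gave 2 to 1279, 0 to 590, 9 to 85 and 1034 to 3070 genes for CAC vs Con at 2, 4, 6 and 8 wk. It gave 0 to 2, 0 to 180, 43 to 367 and 72 to 714 for CAC vs NCAC, and 0 to 0, 0 to 3, 0 to 0 and 0 to 1 for NCAC vs Con. The means gave 2412 to 3538, 1832 to 2991 and 0 to 0, the changes 1 to 18 against Con and 1 to 138 against NCAC, and Con 8 wk vs 2 wk 173 to 2546. List counts were 5 to 10, 8 to 17, 10 to 17 and 15 to 18 for CAC vs Con, 6 to 13, 13 to 20, 10 to 14 and 13 to 18 for CAC vs NCAC, and 7 to 12, 3 to 7, 5 to 8 and 4 to 12 for NCAC vs Con. For the means they were 17 to 23, 16 to 25 and 5 to 15, for the changes 13 to 16 and 10 to 16, and for Con 3 to 8.

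The lists called were 0 in all 18 comparisons with an estimated correlation. By exact permutation of list means, 8 passed at CAC vs Con 8 wk, 3 at CAC vs NCAC 8 wk and 0 in every other comparison of 2 groups. After GC and length correction there were 11 at CAC vs Con 8 wk, 6 at CAC vs NCAC 2 wk, 7 and 10 at NCAC vs Con 2 and 4 wk and 13 for the CAC vs Con mean. With median-of-ratios scaling there were 7 and 4 at NCAC vs Con 2 and 8 wk and 13 for the CAC vs Con mean. Without the rich libraries the NCAC vs Con mean gave 6. With the choroid covariate 197 list calls held and 16 were lost, where the choroid plexus list itself was left out. Of 220, 185 held with median-of-ratios scaling, 202 with the block, 174 without those libraries and 169 after GC and length correction. The direction turned, without passing, for mitochondrially encoded genes in CAC vs Con 2 wk (0.371), NCAC vs Con 2 wk (0.47) and NCAC vs Con 6 wk (0.606) and cytosolic ribosomal protein genes in CAC vs Con 8 wk (0.989) after GC and length correction. It turned for excitatory neuron (0.685) and striatum genes (0.953) in CAC vs NCAC 4 wk without those libraries. No named gene turned direction. Counting error enters only through voom.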

Other observations

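Blood vessel genes moved in opposite directions in CAC. Of 14 endothelial markers at 8 wk against Con, 5 rose and 2 fell, 6 and 4 adjusted over the list alone, so the list as a whole was not called (adjusted p = 0.992). The surface antigen Ly6c1 (0.59 ± 0.12 SE, n = 7 and 5), the blood-brain barrier transporters Slco1a4 (0.42 ± 0.10) and Mfsd2a (0.83 ± 0.21) and the glucose transporter Slc2a1 (0.51 ± 0.13) rose. The VEGF receptor Kdr (−0.63 ± 0.17) and the tight junction protein Cldn5 (−0.55 ± 0.20) fell. Vegfa (−0.51 ± 0.12), Apln (−0.82 ± 0.15) and the endothelin Edn1 (−0.63 ± 0.19), members of the hypoxia and vascular growth list, fell in the same comparison and Hif3a (2.00 ± 0.44) rose. In that list 2 of 15 rose and 3 fell, 2 and 4 adjusted over the list alone (adjusted p = 0.384, direction down, median and mean 0.07). Against NCAC at 8 wk, Ly6c1 (0.71 ± 0.12) and Slco1a4 (0.36 ± 0.10) rose and 0 endothelial markers fell, with 6 rising and 2 falling adjusted over the list alone (adjusted p = 0.207).

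Astrocyte markers were split as well at 8 wk against Con: the glycolytic enzyme Aldoc (0.37 ± 0.07), the growth factor receptor Fgfr3 (0.40 ± 0.10), glutamine synthetase (Glul, 0.35 ± 0.10) and the connexin Gjb6 (0.47 ± 0.16) rose, and the water channel Aqp4 (−0.59 ± 0.15) fell, of 12 (adjusted p = 0.808). Of 16 fasting genes Pdk4, Txnip and Angptl4 rose and Fabp7, Plin2 and Hadha fell (0.411). Of 16 antioxidant genes 3 rose (0.752), of 19 FoxO, autophagy and ubiquitin ligase genes 1 rose and 1 fell (0.844), and of 10 thyroid hormone response genes Klf9 (0.30 ± 0.08) rose and Nrgn (−0.63 ± 0.22) fell (0.411). Of 18 postsynaptic genes 4 rose (0.232), and the lowest adjusted p of that list in any comparison was 0.0512, for CAC against NCAC at 8 wk. Of 8 melanocyte genes 3 were measured in the hippocampus, and Tyrp1 (0.31 ± 0.21), Mitf (0.07 ± 0.14) and Pmel (0.01 ± 0.26) did not pass at 8 wk (list adjusted p = 0.895). No call was made in any comparison for the astrocyte, endothelial, melanocyte, postsynaptic, FoxO, antioxidant and thyroid hormone lists.

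Whether CAC libraries of 8 wk with a higher glucocorticoid response also differ in inflammation or myelin was asked over the 7 libraries, with the outcome written down beforehand, as 2 relations. For the IL6 and STAT3 list r was 0.07 (exact permutation p = 0.926) and rho −0.39 (exact permutation p = 0.396, adjusted 0.396), with r −0.5 without the 2 most distant libraries. For the oligodendrocyte list r was −0.39 (exact permutation p = 0.391) and rho −0.68 (exact permutation p = 0.11, adjusted 0.219), with r −0.74 without the 2 most distant libraries. Over 7 libraries only a very strong relation can pass, so these p decide nothing either way, although the outcome written beforehand took a p over 0.05 as evidence against.

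Some genes were at either of 2 levels across the libraries, also within groups, and the tests on them were chosen only after this was seen. With a gap of at least 2 log2 there were 31 such genes. Cwc22, a splicing factor on chromosome 2 at 77881159 to 77946375, was 400 ± 150 TPM in 13 libraries and 14.6 ± 1.78 in the other 47 (SD), in 4 of 21 CAC, 8 of 19 NCAC and 1 of 20 Con libraries at the high level (Fisher's exact p = 0.0181, two-sided). It passed in 0 comparisons. A hypothesis is that the mice carry different numbers of copies of a stretch of chromosome 2 that holds Cwc22-like predicted genes. In its favour, 57 of 60 libraries were on the same side in Cwc22 and in all 7 copies, and 6 of them were on in the same 13 libraries. Reads shared between copies would leave their sum unchanged, but the summed TPM was 42 times higher in the high libraries, which does not favour that explanation. Nnt, of which C57BL/6J mice carry a deletion, was 16.8 ± 1.1 TPM (14.2 to 19.5) in all 60 libraries. The strain, on which the labels disagree, may thus be neither C57BL6/J nor uniform, which genotypes would have to show, as a shortened Nnt transcript could still give reads.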
